A study of Caenorhabditis elegans with 6 samples.

How the data were processed

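Polyadenylated RNA of whole wild-type L4 larvae was sequenced in 6 libraries, 3 after empty vector RNAi and 3 after rab-11.1 RNAi by feeding, at 20 °C, per the labels' protocols. The labels call the libraries of a group biological replicates 1 to 3. The authors deposited RPKM values (reads per kilobase of transcript, scaled to the depth of the library) for 46739 features in each library, and the reads were paired, per the file headers. The genome build was WBcel235, per the submitters' processing notes. The aligner, the counter, their settings, the annotation release and any use of the strand are not given in the sources used here. The deposited group means, per the file headers, equalled the mean of the 3 RPKM values of each group within 9.1e-13. Of the features, 27248 were at 0 in all libraries and 19491 above 0 in at least 1. Names were matched to the Ensembl release 115 annotation of WBcel235, 41387 by symbol and 2952 by sequence name, and 2400 stayed unmatched and kept the name listed.

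The values are normalized and hold no read counts, so the chosen tests used RPKM, and reads were recovered from the values for read numbers, the voom and thinned settings and the check for copies. The depth of each library was recovered from the steps between RPKM values of features with few reads, at 22946375 to 30183162 reads. With these depths, whole reads in every library were found for 19490 of the 19491 features, the exception being ttn-1. Of these, 2391 were whole at the annotated exon length and 17099 at a length solved from the values. The tolerance was 0.001 reads, wider for solved lengths and at high read numbers. As a control, the same search with wrong depths found whole reads for 8 of 300 features with 20 reads or more in every library. Features with fewer reads were not in this control, so it does not speak to them. Of 4869 features with 2 to 50 reads in their highest library, 1326 (27.2%) were whole in all 6 libraries at the annotated length. Recovered reads summed to 95.3% to 97.8% of the recovered depth, and the RPKM sums ran from 736667 to 778884. Floors of 3 reads cover counting error alone.

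The design fixed before the data were examined held a branch for counts and a branch for normalized values, and the branch for normalized values was used. The alternatives planned for counts alone did not apply. Features at 1 RPKM or more in at least 3 libraries were tested on log2(RPKM + 1) with limma 3.58.1 (R 4.3.3), with eBayes using a trend and robust settings, group as the only term, a two-sided test and Benjamini-Hochberg adjustment at 0.05. All adjusted p values of single genes are from this limma test unless another setting is named. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so none was used for single genes. Means and SDs are of RPKM over 3 libraries.

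The 39 gene lists came from general knowledge of the species and were matched by symbol or sequence name. Lists with at least 5 tested genes were tested with camera of limma, two-sided, at a preset correlation between genes of 0.01, with adjustment over the lists. Beside each list stand its calls over all genes tested and its calls adjusted over the list alone. The lists covered rab GTPases, endosomal recycling and retromer, lysosome, autophagy, the unfolded protein, heat shock, oxidative, osmotic and hypoxia responses, proteasome, immune and pathogen responses, antimicrobial peptides, lysozymes, lectins, insulin signalling, xenobiotic and lipid metabolism, F-box adaptors, vitellogenins, oxidative phosphorylation, ribosomal proteins, histones, collagens, moulting, germline and tissues. Genes named were rab-11.1 and rab-11.2, and the 12 largest increases and 12 largest decreases among protein-coding genes past the threshold, separated by library and at a mean of 5 RPKM or more. Also named were sentinel genes of known responses chosen in advance, and members taken from up to 4 per passing list with the smallest adjusted p in the direction of the list. Outside these rules, passing genes of lists with few calls, and the genes of the ESCRT machinery in the closing section, were named after their values were seen.

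The labels give both groups the replicate numbers 1 to 3. Deviations from the group means across tested genes correlated at 0.40, 0.62 and 0.35 between libraries with the same number. All were above 0.1, so the numbers were taken to pair the samples. However, empty vector replicate 1 correlated more with the library labelled rab-11.1 RNAi replicate 3 (0.46). Empty vector replicate 3 and rab-11.1 RNAi replicate 1 correlated at 0.18. The crossed pairs of replicates 1 and 3 thus also met the rule, which cannot show that these replicates pair by number. These correlations are across genes, which are not independent replicates. The fit with the replicate number as a block was an alternative fixed in advance. No library was a copy of another, since the chi-square per degree of freedom between recovered reads of replicates ran from 11.2 to 63.6.

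Alternatives fixed in advance were no filter, a filter at 5 RPKM, pseudocounts of 0.1 and 5, the replicate block, each library left out in turn, eBayes without the trend, a fold of at least 2, camera with an estimated correlation, fry in place of camera, and lists without shared members. Added after the data were seen were median-of-ratios scaling, quantile normalization, limma-voom on recovered reads, reads thinned to the lowest depth, both replicate 2 libraries left out, the block with both replicate 3 libraries left out, and a germline index as a covariate. The scripts were tested on simulated data before use. With 200 genes changed among 13784 tested and a biological coefficient of variation of 0.15, in 5 simulated runs of this comparison, 97.6% of 2-fold and 100% of 4-fold changes were recovered, with 5.8% false among the called genes. A list shifted 1.5-fold was called in 5 of 5 runs and 0 of 190 other list tests were called. The simulation drew every gene independently, so it cannot show how often camera calls unshifted lists whose genes are correlated. It also gave all genes the same variation and no offset of replicate 2, so its rates for single genes may not hold in the data. In the data the estimated correlation within lists reached 0.91, in the vitellogenins. Recovery of depth was tested on 3 simulated libraries of 18831 features, with a largest relative error of 2.2e-16. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading, matching and figures.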

Results

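Whole L4 larvae of wild-type Caenorhabditis elegans were compared after RNA interference (RNAi) by feeding, in which worms eat bacteria that make double-stranded RNA against a chosen gene. Polyadenylated RNA was sequenced from 3 libraries of worms fed the empty vector, which targets no worm gene, and from 3 libraries of worms fed the rab-11.1 clone. The gene rab-11.1 encodes a small GTPase of recycling endosomes. All worms were kept at 20 °C. The libraries held 30183162, 30006006 and 27190567 reads for empty vector replicates 1, 2 and 3, and 22946375, 23345432 and 25107994 reads for rab-11.1 RNAi replicates 1, 2 and 3, as recovered from the steps between the deposited values. A single read on a transcript of 1 kb therefore stood for 0.0331 to 0.0436 RPKM (reads per kilobase of transcript, scaled to the depth of the library), and 3 reads, taken as the floor, for 0.099 to 0.131 RPKM. Levels of the tested genes correlated at 0.973 to 0.993 across genes between libraries of the same group. The first principal component held 65.3% of the variance and parted the groups, with the empty vector libraries at -39.1, -6.4 and -33.7 and the rab-11.1 RNAi libraries at 17.3, 50.5 and 11. Replicate 2 of each group lay apart from the other replicates on the next component (19.1% of the variance), at 31.2 and 8.8, against -18.5 to 0.4 in the other 4 libraries.

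The question asked was which transcripts change when rab-11.1 is targeted, and the target was read in every library. The gene rab-11.1 (WBGene00004274, WBcel235 chromosome I, 108682 to 110057, minus strand, protein coding) stood at 411.1, 398.2 and 409.5 RPKM in the empty vector libraries (406.2 ± 7.01, SD, n = 3). It was low in rab-11.1 RNAi replicates 1 and 2, at 151.3 and 137.8 RPKM, which were 37.2% and 33.9% of the empty vector mean. In the library labelled rab-11.1 RNAi replicate 3 it was high, at 632.6 RPKM or 155.7% of the empty vector mean. That library goes against its label for the target gene, and every direction given here for the rab-11.1 RNAi group includes it. These levels rested on 15484, 14912 and 13895 reads in the empty vector libraries and on 4333, 4014 and 19823 reads in the rab-11.1 RNAi libraries. The group difference did not pass the threshold (log2 fold change -0.78, SE 0.55, adjusted p = 0.415). Without the library labelled rab-11.1 RNAi replicate 3 it did (log2 fold change -1.49, SE 0.09, adjusted p = 0.00557), with the empty vector mean 2.81 times the mean of the other 2 libraries. Reads of the double-stranded RNA made by the bacteria can be counted on the targeted part of the gene, and the deposited values do not separate them from transcript.

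The paralogue rab-11.2 (WBGene00004275, chromosome I, 11632983 to 11638491, protein coding) rose. It was listed at 0, 0.136 and 0.20 RPKM in the empty vector libraries (0, 3 and 4 reads) and at 1.96, 2.74 and 2.06 RPKM after rab-11.1 RNAi (33, 47 and 38 reads), with a log2 fold change of 1.55 (SE 0.17, adjusted p = 0.00386). It passed without any single empty vector library and fell below the filter in the fits that left out a rab-11.1 RNAi library. Its level in the library labelled rab-11.1 RNAi replicate 3 lay between those of replicates 1 and 2. Its exons overlap W04G5.10 on the same strand, and reads of this overlap cannot be assigned to either gene.

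**Figure D1:**
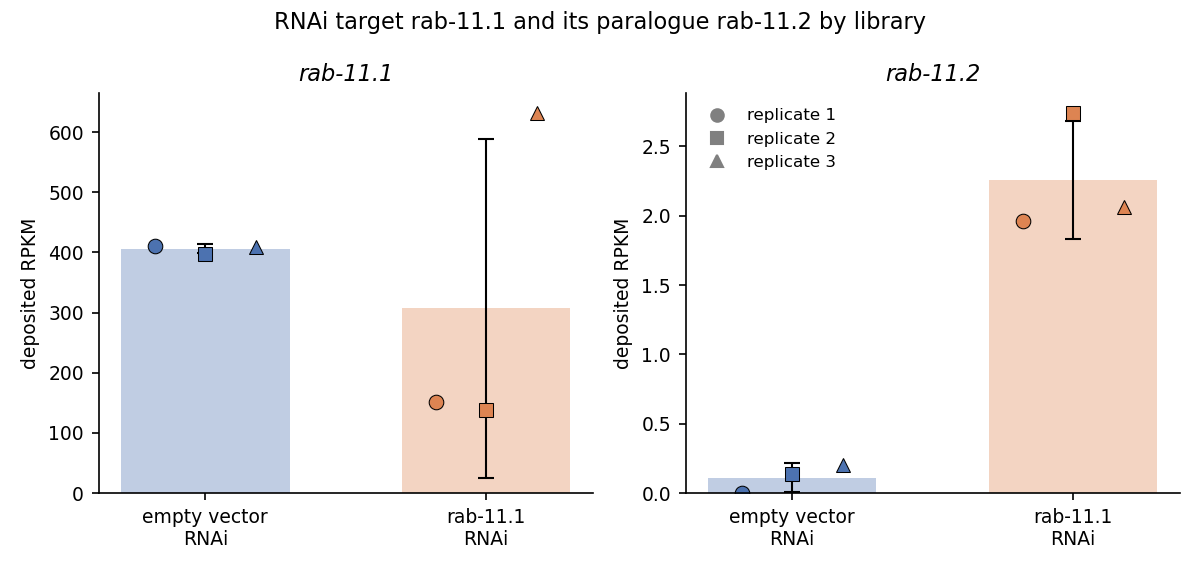
Deposited RPKM of rab-11.1 and of its paralogue rab-11.2 in each library, with bars at the mean of 3 libraries and error bars of 1 SD. The library labelled rab-11.1 RNAi replicate 3 stands at 632.6 RPKM for rab-11.1, above all 3 empty vector libraries, and at 2.06 RPKM for rab-11.2, among the other rab-11.1 RNAi libraries.

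The largest increases were those of genes at a mean of 15.6 RPKM or less in the empty vector libraries. The tubulin gene tbb-6 rose from 4.62 ± 0.307 to 242 ± 128 RPKM (SD, n = 3), a 52.4-fold increase (log2 fold change 5.32, SE 0.32, adjusted p = 0.00115). Y41C4A.11 rose 41.4-fold, from 3.89 ± 0.332 to 161 ± 33 RPKM (log2 fold change 5.03, SE 0.15, adjusted p = 0.000121). Y37H2A.14 rose 32.2-fold to 306 RPKM, C08E8.4 rose 28.4-fold to 137 RPKM and F33H12.7 rose 14.3-fold to 223 RPKM. Y58A7A.5 reached 102 RPKM, srlf-34 (listed as ZK970.7) 58.7 RPKM, T26H5.9 50.9 RPKM, F57B9.3 23.7 RPKM and ZC239.14 21.1 RPKM. F22E5.6 and sdz-35 rose from 0.235 and 0.225 RPKM to 14.9 and 13.9 RPKM. Of these 12 genes, F57B9.3, F22E5.6, ZC239.14 and sdz-35 fell below the filter in the fits that left out a rab-11.1 RNAi library and were not tested there. The others passed the threshold in every fit that left out 1 library (highest adjusted p = 0.0365), including the fit without the library labelled rab-11.1 RNAi replicate 3. F57B9.3 lies antisense to abu-13, ZK970.7 to gcy-5 and Y58A7A.5 to the noncoding gene Y58A7A.7, and the sources do not state whether counting used the strand.

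Yolk protein and cuticle collagen genes held the largest decreases. The vitellogenin genes vit-3, vit-4 and vit-5 fell 27.1-fold, 35.6-fold and 32.8-fold, to 4.16, 1.76 and 1.74 RPKM. For vit-3 this was a change from 113 ± 65.7 to 4.16 ± 3.59 RPKM (log2 fold change -4.42, SE 0.66, adjusted p = 0.0117). The library labelled rab-11.1 RNAi replicate 3 held the most of all 3 genes in its group, at 8.297, 3.742 and 2.722 RPKM. In rab-11.1 RNAi replicates 1 and 2 vit-3 stood at 2.142 and 2.027 RPKM. There vit-4 stood at 0.8403 and 0.7029 RPKM and vit-5 at 0.492 and 2.005 RPKM. The folds depend in part on that library. The collagen genes col-7, col-62 and col-179 fell to 1.67, 2.59 and 2.84 RPKM, grl-27 fell to 3.14 RPKM and pud-4 to 4.51 RPKM. BE0003N10.6 fell 9.97-fold, from 139 ± 27.1 to 14 ± 4.04 RPKM (log2 fold change -3.25, SE 0.24, adjusted p = 0.0018). Y71G12B.18 fell 8.96-fold, and the neighbouring genes D1014.7 and D1014.6 fell 7.05-fold and 5.48-fold. BE0003N10.6, Y71G12B.18, D1014.7 and D1014.6 passed in every fit that left out 1 library (highest adjusted p = 0.0397). The others did not. Without empty vector replicate 1 or 3, or without rab-11.1 RNAi replicate 1, the calls of vit-3, vit-4, vit-5, col-7, col-62, grl-27, pud-4 and col-179 ended, with highest adjusted p values of 0.063, 0.0721, 0.127, 0.153, 0.157, 0.155, 0.137 and 0.149. Leaving out rab-11.1 RNAi replicate 2 or the library labelled replicate 3 also ended those of vit-5, col-7, grl-27 and col-179. Leaving out replicate 2 ended that of col-62, and leaving out the library labelled replicate 3 that of pud-4. With limma-voom on recovered reads vit-5, col-7, col-62, grl-27 and col-179 did not pass (adjusted p = 0.0951, 0.181, 0.148, 0.104 and 0.0985). With no filter the calls of col-7, col-62, grl-27 and col-179 ended (adjusted p = 0.0559 to 0.0598), and without the trend those of the same genes and pud-4 (adjusted p = 0.0503 to 0.0608). With a pseudocount of 5 col-7 and grl-27 did not pass, nor col-62 with a pseudocount of 0.1 (highest adjusted p = 0.0553). With the replicate block and both replicate 3 libraries left out vit-5 and pud-4 did not pass (adjusted p = 0.0889 and 0.121). In that setting vit-4 and col-7 fell below the filter. Vitellogenin and collagen genes are close paralogues whose reads may be shared, vit-3 and vit-4 lie antisense to noncoding genes, and col-179 lies antisense to C34F6.11.

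**Figure D2:**
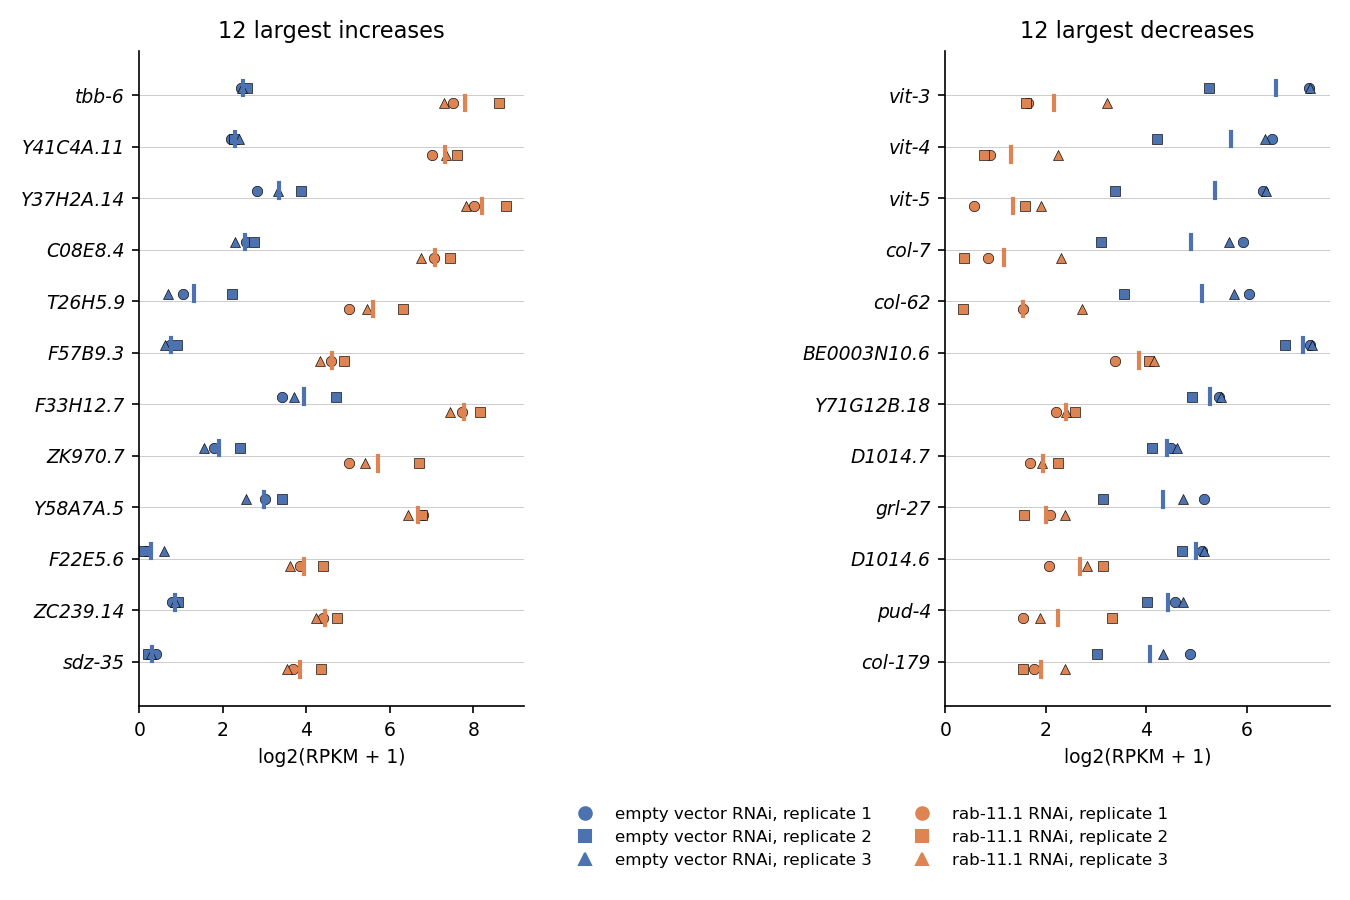
Level of the 12 genes with the largest increases and the 12 with the largest decreases, as log2(RPKM + 1) in each library, with short lines at the group means. The libraries of the groups do not overlap for any of these genes, and empty vector replicate 2 lies toward the rab-11.1 RNAi libraries for vit-3, vit-4, vit-5, col-7 and col-62.

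Across the genome more genes rose than fell. Of 13833 features tested (13283 protein coding), 1245 passed an adjusted p of 0.05 by limma, 1097 higher and 148 lower after rab-11.1 RNAi, so that 88.1% of the called genes were higher. At a fold of 2 or more there were 398 higher and 38 lower genes. In all 1245 the 3 libraries of one group lay above the 3 of the other, which was the case for 33.9% of all features tested against 10% by chance. Calls that held in every fit leaving out 1 library numbered 229 higher and 18 lower. The median log2 fold change of all tested features was 0.09. Rescaling by median-of-ratios factors moved it to -0.02, with 552 higher and 284 lower genes (66% higher), and quantile normalization moved it to -0.04, with 524 higher and 249 lower (67.8% higher). With the replicate number as a block, 2906 genes passed, 2288 higher and 618 lower, among them all 1245. With the block and both replicate 3 libraries left out, a setting chosen after the result was seen, the genes changed numbered 915, 753 higher and 162 lower, of which 628 were among the 1245. Of the named genes below, gst-4, irg-4, nlp-29, rab-39, rps-2, unc-52, snb-1, elt-3 and dlg-1 did not pass with no filter (adjusted p = 0.0565 to 0.0671) or without the trend (adjusted p = 0.0595 to 0.11), nor did rab-1, rab-10, snx-1, rpn-12 and hmr-1 without the trend (adjusted p = 0.0506 to 0.0757). With the block and both replicate 3 libraries left out, hsp-4, gst-4, rab-1, rab-10, rab-39, tbc-2, snx-1, atg-3, ire-1, rpn-12, rps-2, unc-52, snb-1, hmr-1, dlg-1 and his-21 did not pass (adjusted p = 0.0534 to 0.194). With limma-voom gst-4, nlp-29 and rab-39 did not pass either (adjusted p = 0.054 to 0.067). Nor did rab-39 with thinned reads (adjusted p = 0.0647), or unc-52 and dlg-1 with both replicate 2 libraries left out (adjusted p = 0.0523 and 0.068). Fold increases and decreases are ratios of mean RPKM, whereas log2 fold changes and tests were computed on log2(RPKM + 1), which understates changes of genes at low levels.

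Of 39 gene lists fixed from general knowledge before the data were examined, 25 passed by camera with its preset correlation, 15 up and 10 down. With a correlation estimated from the data none of the 39 did (lowest adjusted p = 0.341), and 3 had an unadjusted p under 0.05. Splits of the libraries that mix the groups passed 11 to 21 lists by camera with its preset correlation. The fry test, which asks whether a list's genes move on balance in 1 direction, passed 16. Camera instead ranks a list against all other tested genes, and the median log2 fold change of all tested features was 0.09. A list marked down may therefore have moved less than the rest without falling itself. Of the 25 lists past camera, fry did not pass the epidermal antimicrobial peptide, SKN-1, vitellogenin, oxidative phosphorylation, ribosomal, adult epidermis, neuronal, body wall muscle, pharynx and 3 germline lists. The median levels of the single libraries overlapped between the groups in the endosomal recycling, endoplasmic reticulum, epidermis, neuronal, pharynx, oxidative phosphorylation, ribosomal and 3 germline lists. All list directions given here held in sign of the median under both rescalings, except where stated.

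Genes of the intracellular pathogen response rose. Of its 64 genes 25 were tested, of which 13 rose, 0 fell and 12 did not pass. Adjusted over the list alone 21 rose (median log2 fold change 0.78). Genes under 1 RPKM in every empty vector library passed the filter only where all rab-11.1 RNAi libraries reached 1 RPKM. Such genes could be counted as rising but hardly as falling. Camera gave an adjusted p of 2.02e-11, adjusted p = 4.83e-05 with no filter and adjusted p = 0.341 with an estimated correlation. Among them pals-24 (listed as C29F9.4) rose 3.2-fold to 54.6 RPKM, pals-6 (listed as C17H1.7) rose from 0.348 to 7.41 RPKM, the cullin gene cul-6 rose 3.74-fold to 15 RPKM and fbxa-158 rose from 0.142 to 4.38 RPKM. The calls of pals-24 and cul-6 held in every fit that left out 1 library, whereas pals-6 and fbxa-158 fell below the filter in the fits that left out a rab-11.1 RNAi library and held in the other 3. The sentinel pals-5 (listed as C17H1.6) was below the filter, at 0.0101 and 0.0743 RPKM, and was not tested. F-box and MATH adaptor genes of ubiquitin ligases moved with them. Of 484 genes 179 were tested, of which 51 rose and 0 fell, and 62 rose adjusted over the list alone (median 0.29). Camera gave an adjusted p of 1.4e-06, adjusted p = 0.00224 with no filter and adjusted p = 0.341 with an estimated correlation. The members fbxa-98, fbxa-60 and fbxc-58 (listed as C10C5.2) rose 5.82-fold, 4.55-fold and 9.04-fold. F-box genes are a family of close paralogues, so reads may be shared among them.

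Of the other lists of immune and antimicrobial genes the ZIP-2, PMK-1 and epidermal peptide lists passed, whereas the lysozyme and C-type lectin lists, given with the remaining lists, did not (camera adjusted p = 0.0608, up, and 0.0778, down). Of 9 tested genes of the ZIP-2 surveillance list, 5 rose and 0 fell, and 8 rose adjusted over the list alone (median 1.08, camera adjusted p = 2.26e-05, and adjusted p = 0.341 with an estimated correlation). Its regulator zip-2 rose, its members irg-1, irg-2 and oac-14 rose 3.36-fold, 6.04-fold and 5.49-fold, and cebp-1 rose 2.6-fold but did not pass without empty vector replicate 3 (adjusted p = 0.063). The list for the p38 kinase PMK-1 held genes dependent on it and also sek-1, nsy-1, pmk-1 and atf-7 of the pathway itself. Of 26 genes tested, 12 rose and clec-86 fell, and 17 rose and 1 fell adjusted over the list alone (median 0.69, camera adjusted p = 0.00012, and adjusted p = 0.341 with an estimated correlation). In this list dod-22 rose 4.21-fold, clec-67 2.59-fold, lys-2 2.43-fold to 510 RPKM and C17H12.8 3.26-fold to 522 RPKM, each in every fit that left out 1 library. Of 32 tested epidermal antimicrobial peptide genes, 8 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.56, camera adjusted p = 0.00106, and adjusted p = 0.611 with an estimated correlation). A fit with the replicate block gave 16 higher and 1 lower. The members cnc-4, nlp-30 and nlp-34 rose 8.33-fold, 2.62-fold and 2.54-fold, and nlp-25 rose 4.79-fold but did not pass without empty vector replicate 1 (adjusted p = 0.0533) and was below the filter without any single rab-11.1 RNAi library. Among single sentinels lys-7 rose 7.37-fold, from 30.3 ± 1.63 to 223 ± 43.8 RPKM (adjusted p = 0.000741), and it passed in every fit that left out 1 library. The sentinels irg-4 (listed as F08G5.6), irg-5 (listed as F35E12.5) and nlp-29 rose 2.5-fold, 4.96-fold and 3.57-fold. They lost their calls without empty vector replicate 1, empty vector replicate 3 or the library labelled rab-11.1 RNAi replicate 3, irg-4 and irg-5 also without empty vector replicate 2, and nlp-29 also without rab-11.1 RNAi replicate 1 or 2. Their highest adjusted p values were 0.13, 0.0983 and 0.15. With median-of-ratios scaling irg-4 and nlp-29 did not pass (adjusted p = 0.063 and 0.0606), nor did they with quantile normalization (adjusted p = 0.0505 and 0.0613). The sentinels sysm-1 (listed as T24B8.5, adjusted p = 0.118) and cnc-2 (adjusted p = 0.18) did not pass, and sysm-1 passed with the replicate block (adjusted p = 0.0199). The lysozyme gene ilys-3 was below the filter, at 0.196 and 1.68 RPKM.

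Autophagy genes rose. Of 28 tested, 13 rose and 0 fell, and 21 rose adjusted over the list alone (median 0.48, camera adjusted p = 2.02e-07, and adjusted p = 0.341 with an estimated correlation). The receptor gene sqst-1 rose 4.1-fold, from 36.2 ± 5.53 to 148 ± 31.5 RPKM (adjusted p = 0.00235), and passed in every fit that left out 1 library. The ubiquitin-like gene lgg-1 rose 2.41-fold to 581 RPKM, atg-18 1.63-fold, vps-34 1.48-fold and atg-3 1.36-fold. These 4 did not pass without empty vector replicate 1, empty vector replicate 3 or rab-11.1 RNAi replicate 1, and atg-3 not without the library labelled replicate 3 either (highest adjusted p values of 0.109, 0.0741, 0.0735 and 0.0827). With median-of-ratios or quantile scaling atg-3 did not pass (adjusted p = 0.0555 and 0.0642). The regulator hlh-30 did not pass (adjusted p = 0.372).

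Membrane traffic genes rose in part. Of 35 tested genes of endosomal recycling and retromer, 7 rose and 0 fell, and 17 rose adjusted over the list alone (median 0.20, camera adjusted p = 0.000818, and adjusted p = 0.341 with an estimated correlation). In the blocked fit 14 rose. The gene alx-1 rose 2.47-fold, from 47.2 ± 2.57 to 117 ± 18.8 RPKM, in every fit that left out 1 library, and it lies antisense to R10E12.2. The genes ral-1, tbc-2 and snx-1 rose 1.59-fold, 1.41-fold and 1.38-fold, but none passed without empty vector replicate 1 or 3, nor tbc-2 and snx-1 without rab-11.1 RNAi replicate 1, nor tbc-2 without the library labelled replicate 3 (highest adjusted p values of 0.066, 0.102 and 0.119). With either rescaling tbc-2 and snx-1 did not pass (lowest adjusted p = 0.0599 and 0.0806). Of 20 tested rab GTPase genes, 4 rose and 0 fell, and 13 rose adjusted over the list alone (median 0.30, camera adjusted p = 0.000657, and adjusted p = 0.45 with an estimated correlation). In the blocked fit 9 rose. Beside rab-11.2 these were rab-1, rab-10 and rab-39, which rose 1.28-fold, 1.52-fold and 1.29-fold. They lost their calls with either rescaling and without any single empty vector library or the library labelled rab-11.1 RNAi replicate 3, and rab-1 and rab-39 also without rab-11.1 RNAi replicate 1 or 2, with highest adjusted p values of 0.143, 0.128 and 0.139 among the fits that left out 1 library.

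Of 30 tested genes of the endoplasmic reticulum unfolded protein response, 6 rose and 0 fell, and 13 rose adjusted over the list alone (median 0.18, camera adjusted p = 0.00556, and adjusted p = 0.341 with an estimated correlation). With the replicate block 10 rose and 1 fell, and with median-of-ratios scaling the list did not pass (adjusted p = 0.0928). The regulators xbp-1 and ire-1 rose 1.79-fold and 1.47-fold in every fit that left out 1 library, although ire-1 lies antisense to unc-105. The genes ckb-2 and hsp-4 rose 2.61-fold and 1.54-fold. The call of ckb-2 ended without empty vector replicate 1 (adjusted p = 0.0611), and that of hsp-4 without any single library except empty vector replicate 2 (highest adjusted p = 0.0823). Of 33 tested proteasome genes only rpn-12 rose, 1.25-fold, and it lost its call without any single library (highest adjusted p = 0.133) and with either rescaling. Adjusted over the list alone 8 rose (median 0.16, camera adjusted p = 0.000241, and adjusted p = 0.341 with an estimated correlation), 2 rose with the replicate block, and with median-of-ratios scaling the list did not pass (adjusted p = 0.176). Of 24 tested SKN-1 oxidative stress targets, 7 rose and gst-4 and gst-10 fell, and 10 rose and 2 fell adjusted over the list alone (median 0.37, camera adjusted p = 0.0061, and adjusted p = 0.566 with an estimated correlation). Here gst-7 rose 2.25-fold, and aip-1 and gst-39 rose 2.17-fold and 2.43-fold but did not pass without empty vector replicate 3 (adjusted p = 0.0511 and 0.063). In contrast gst-4 fell from 50.2 ± 9.03 to 33.8 ± 1.13 RPKM (adjusted p = 0.0442), a call that ended without any single library except empty vector replicate 2 (highest adjusted p = 0.117), and gcs-1 did not pass (adjusted p = 0.374).

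Of 26 tested DAF-16 targets of insulin signalling, 8 rose and asns-2 fell, and 11 rose and 1 fell adjusted over the list alone (median 0.32, camera adjusted p = 0.0483, and adjusted p = 0.341 with an estimated correlation). The list did not pass with the replicate block (adjusted p = 0.0978, with 11 higher and 2 lower genes) or without empty vector replicate 3, rab-11.1 RNAi replicate 1 or the library labelled replicate 3 (highest adjusted p = 0.0815). It also did not pass with a filter at 5 RPKM (adjusted p = 0.185), thinned reads (adjusted p = 0.0506), the germline index as a covariate (adjusted p = 0.139), the block without both replicate 3 libraries (adjusted p = 0.14) or only members of no other list (adjusted p = 0.493). Beside lys-7, dod-3 rose 5.68-fold, and fat-5 and lea-1 rose 2.28-fold and 1.51-fold but did not pass without empty vector replicate 3 (adjusted p = 0.0537 and 0.0523). The sentinels sod-3 (adjusted p = 0.96) and mtl-1 (adjusted p = 0.198) did not pass. The mitochondrial chaperone genes hsp-6 and hsp-60 did not pass (adjusted p = 0.276 and 0.109), nor did the heat shock genes hsp-16.2 and hsp-70 (adjusted p = 0.102 and 0.742). The mitochondrial unfolded protein response list did not pass either (drp-1 and cdr-2 of 21 tested rose and 0 fell, 3 rose adjusted over the list alone, median -0.06, adjusted p = 0.101, and 4 rose with the replicate block), but passed, down, without empty vector replicate 1 or 3 (adjusted p = 0.0259 and 0.0352). The same was true in all 6 libraries of the cytosolic heat shock list (hsp-16.11, hsp-17, hsp-43 and hsf-1 of 24 tested rose and 0 fell, 8 rose adjusted over the list alone, median 0.36, adjusted p = 0.101, and 8 rose with the replicate block). That list passed, up, without empty vector replicate 3 (adjusted p = 0.0176), without the library labelled rab-11.1 RNAi replicate 3 (adjusted p = 0.0248), with no filter (adjusted p = 0.0329), with quantile normalization (adjusted p = 0.0123) and with the block without both replicate 3 libraries (adjusted p = 0.00243).

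Of 53 tested core and linker histone genes, 8 rose and 0 fell, and 18 rose adjusted over the list alone (median 0.40, camera adjusted p = 0.00289, and adjusted p = 0.45 with an estimated correlation). With the replicate block 18 rose. The gene his-21 rose 1.78-fold in every fit that left out 1 library, and his-17 rose 2.34-fold but did not pass without empty vector replicate 3 (adjusted p = 0.0635). Histone genes are near-identical copies, so their single values are uncertain. As polyadenylated RNA was sequenced, the values speak of polyadenylated histone RNA alone and not of all histone transcripts. Of 22 tested genes of the epidermis 4 rose and 0 fell, and 4 rose adjusted over the list alone (median 0.28, camera adjusted p = 0.0407, and adjusted p = 0.566 with an estimated correlation). These were hmr-1, sta-2, elt-3 and dlg-1, which rose 1.35-fold, 2.28-fold, 1.55-fold and 1.24-fold and lost their calls with either rescaling and without empty vector replicate 1, empty vector replicate 3 or rab-11.1 RNAi replicate 1 (highest adjusted p values of 0.112, 0.13, 0.154 and 0.158). The list itself did not pass without empty vector replicate 3, rab-11.1 RNAi replicate 1 or rab-11.1 RNAi replicate 2 (highest adjusted p = 0.109) or with median-of-ratios or quantile scaling (adjusted p = 0.0969 and 0.054). Nor did it pass with a filter at 5 RPKM (adjusted p = 0.112), the germline index as a covariate (adjusted p = 0.0584) or only members of no other list (adjusted p = 0.193), and 8 genes rose with the replicate block. Of 63 tested neuronal genes snb-1 rose, 1.79-fold, and 0 passed adjusted over the list alone (median 0.27, camera adjusted p = 0.00556, and adjusted p = 0.633 with an estimated correlation). The call of snb-1 ended with either rescaling and without any single library except rab-11.1 RNAi replicate 2 (highest adjusted p = 0.153). The neuronal list did not pass without empty vector replicate 1 or rab-11.1 RNAi replicate 2 (highest adjusted p = 0.111), and with the replicate block 18 of its genes rose and 1 fell.

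Of 6 tested vitellogenin genes 3 fell and 0 rose, and 5 fell adjusted over the list alone (median -2.91, camera adjusted p = 1.4e-06, and adjusted p = 0.341 with an estimated correlation). The gene vit-2 did not pass (336 ± 209 and 125 ± 22.4 RPKM, adjusted p = 0.26) but passed without empty vector replicate 2 (adjusted p = 0.00464). Of 133 tested cuticle collagen genes 9 fell and 0 rose, the same number adjusted over the list alone (median -0.29, camera adjusted p = 3.6e-12, and adjusted p = 0.341 with an estimated correlation). Empty vector replicate 2 lay toward the rab-11.1 RNAi libraries in this list, with a median log2 level of 7.28 against 7.96 and 7.74 in empty vector replicates 1 and 3 and 7.05 to 7.18 after rab-11.1 RNAi. The replicate block gave 54 lower and 6 higher genes. The abundant col-107 fell from 951 ± 82.9 to 656 ± 45.9 RPKM and col-156 fell 1.75-fold. The call of col-107 ended without empty vector replicate 1 or any single rab-11.1 RNAi library, and that of col-156 without any single empty vector library or rab-11.1 RNAi replicate 2 (highest adjusted p values of 0.0823 and 0.108). Of 7 tested genes of the adult and late larval epidermis 2 fell, col-7 and col-62, and 3 fell adjusted over the list alone (median -0.19, mean -1.51, camera adjusted p = 0.00556, and adjusted p = 0.341 with an estimated correlation). The adult collagen gene col-19 stood at 166 ± 107 and 23 ± 23.3 RPKM and did not pass (adjusted p = 0.107), but it passed with the replicate block (adjusted p = 0.00358).

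Germline lists ranked lower by camera without any single gene falling in the fit by group alone. Of 86 tested spermatogenesis genes spe-48 (listed as Y51F10.10) rose and 0 fell, and 0 passed adjusted over the list alone (median -0.22, camera adjusted p = 2.48e-05, and adjusted p = 0.633 with an estimated correlation). Of 30 tested genes of oogenesis and eggshell 0 passed, also adjusted over the list alone (median -0.26, camera adjusted p = 0.00148, and adjusted p = 0.633 with an estimated correlation). Of 44 tested genes of germline proliferation and meiosis 0 passed, also adjusted over the list alone (median -0.16, camera adjusted p = 2.48e-05, and adjusted p = 0.633 with an estimated correlation). With the replicate block 17, 9 and 12 genes fell in these lists. Without rab-11.1 RNAi replicate 2 neither the spermatogenesis list (adjusted p = 0.0958) nor the oogenesis list (adjusted p = 0.111) passed. Replicate 2 of both groups stood apart in these lists. The mean of their 160 genes, set to the empty vector mean on the log2 scale, was 0.32, -0.54 and 0.22 in the empty vector libraries and -0.01, -0.64 and 0.09 in the rab-11.1 RNAi libraries. The germline genes msp-3 and rme-2 did not pass (adjusted p = 0.651 and 0.512) and passed with the replicate block (adjusted p = 0.0367 and 0.0387).

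**Figure D3:**
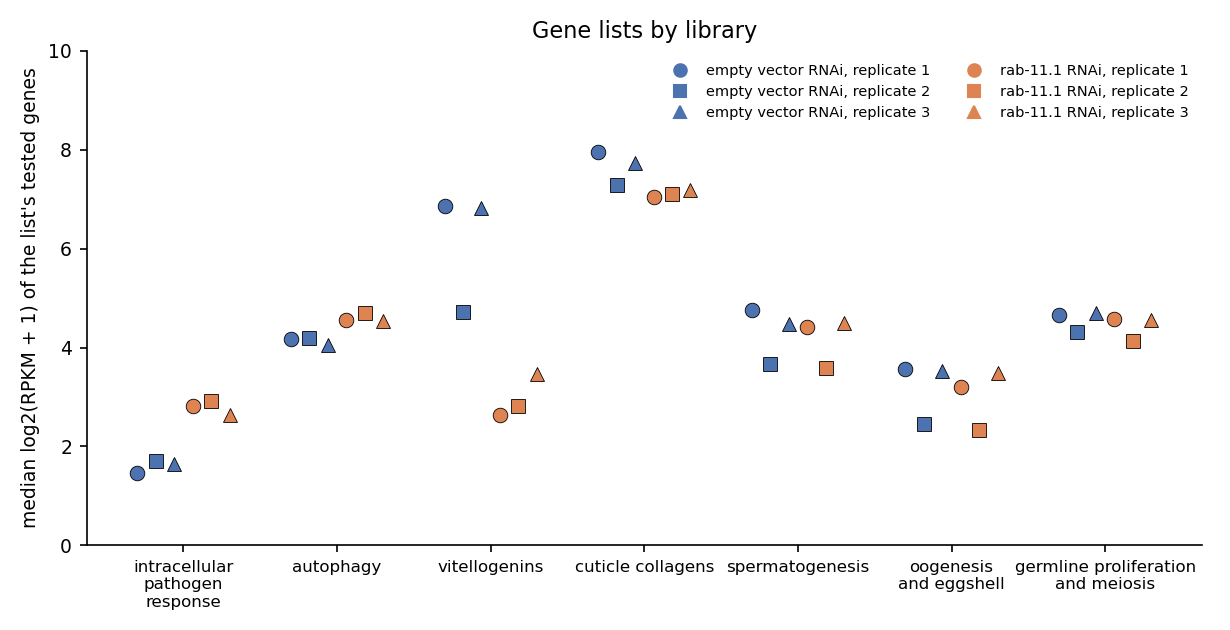
Median log2(RPKM + 1) of the tested genes of 7 lists in each library, 3 libraries per group. The intracellular pathogen response and autophagy medians of the rab-11.1 RNAi libraries lie above those of the empty vector libraries, whereas replicate 2 of both groups lies lowest in the 3 germline lists.

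Pharynx genes ranked lower by camera, and muscle and housekeeping genes did so with small shifts. Of 32 tested pharynx genes 0 passed, also adjusted over the list alone (median -0.45, camera adjusted p = 1.09e-06, and adjusted p = 0.341 with an estimated correlation), and 12 fell and 3 rose with the replicate block. The libraries overlapped in this list, with median log2 levels of 4.9, 4.28 and 4.73 in the empty vector libraries and 3.94, 3.68 and 4.55 in the rab-11.1 RNAi libraries. Of 30 tested body wall muscle genes unc-52 fell, from 94.2 to 75.5 RPKM, and 0 passed adjusted over the list alone (median -0.08, camera adjusted p = 1.48e-05, and adjusted p = 0.341 with an estimated correlation). The call of unc-52 ended without any single library (highest adjusted p = 0.148), and with the replicate block 2 genes of the list fell. Of 48 tested nuclear-encoded genes of oxidative phosphorylation 0 passed, also adjusted over the list alone (median -0.10, camera adjusted p = 3.57e-06, and adjusted p = 0.566 with an estimated correlation), and 2 fell with the replicate block. That list did not pass without both replicate 2 libraries (adjusted p = 0.0718). Of 81 tested cytosolic ribosomal protein genes rps-2 fell, from 2317 to 1889 RPKM, and 0 passed adjusted over the list alone (median -0.01, camera adjusted p = 0.00146, and adjusted p = 0.682 with an estimated correlation). The call of rps-2 ended without any single library (highest adjusted p = 0.199), with quantile normalization (adjusted p = 0.0804), no filter (adjusted p = 0.067), a pseudocount of 5 (adjusted p = 0.0539), no trend (adjusted p = 0.11), thinned reads (adjusted p = 0.0507) and both replicate 2 libraries left out (adjusted p = 0.0661). The ribosomal list did not pass without empty vector replicate 2 or rab-11.1 RNAi replicate 1 (highest adjusted p = 0.51) or without both replicate 2 libraries (adjusted p = 0.102). With quantile normalization it did not pass (adjusted p = 0.188) and its median was 0.03.

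The remaining lists did not pass with all 6 libraries and the chosen scale. Of 187 tested genes of xenobiotic metabolism 40 rose and 12 fell, and 46 rose and 20 fell adjusted over the list alone (median 0.24, adjusted p = 0.183). This list passed, up, with median-of-ratios and quantile scaling (adjusted p = 0.0322 and 0.0357), without empty vector replicate 2 (adjusted p = 0.0211) and with fry (adjusted p = 0.0424). Of 101 tested C-type lectin genes 11 rose and clec-51, clec-56, clec-86, clec-170 and clec-258 fell, 15 rose and 6 fell adjusted over the list alone (median -0.02, adjusted p = 0.0778), and 17 rose and 10 fell with the replicate block. The lectin list passed, down, without rab-11.1 RNAi replicate 1 (adjusted p = 0.04998). Of 33 tested lysozyme and saposin-like genes 9 rose and spp-4 fell, 12 rose and 2 fell adjusted over the list alone (median 0.42, adjusted p = 0.0608), and 14 rose and 1 fell with the replicate block. It passed, up, with median-of-ratios and quantile scaling (adjusted p = 0.0179 and 0.0018), without empty vector replicate 2 or both replicate 2 libraries (adjusted p = 0.0211 and 0.018), with no filter (adjusted p = 0.0243) and with fry (adjusted p = 0.00582). Of 32 tested actin and apical junction genes 7 rose and 0 fell, 15 rose and 3 fell adjusted over the list alone (median 0.17, adjusted p = 0.409), and 11 rose and 2 fell with the replicate block, while fry passed the list, up (adjusted p = 0.00354). Of 47 tested lysosome and v-ATPase genes scav-3, glo-1, asp-4 and ppk-3 rose and vha-6 and gba-4 fell, 7 rose and 3 fell adjusted over the list alone (median 0.02, adjusted p = 0.196), and 9 rose and 3 fell with the replicate block. Without empty vector replicate 1 it passed, down (adjusted p = 0.0259). Of 28 tested intestinal genes pgp-1, gem-4, cpr-1 and dct-17 rose and vha-6 and aqp-4 fell, 4 and 2 also adjusted over the list alone (median -0.08, mean 0.18, adjusted p = 0.257), and the list passed, down, without empty vector replicate 1 (adjusted p = 0.0446). Of 61 tested genes of fatty acid beta-oxidation and lipases acs-4 rose and acs-5 fell, 0 passed adjusted over the list alone (median 0.01, adjusted p = 0.0685), and 7 rose and 3 fell with the replicate block. It passed, down, without empty vector replicate 1 or 3 (adjusted p = 0.0107 and 0.0491). Of 22 tested genes of fatty acid synthesis fat-5 and sbp-1 rose and 0 fell, 4 rose and 1 fell adjusted over the list alone (median 0.09, adjusted p = 0.886), and 4 rose and 1 fell with the replicate block.

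Of 16 tested osmotic stress genes nlp-29 and dod-3 rose and hmit-1.3 fell, 3 rose and 2 fell adjusted over the list alone (median 0.31, adjusted p = 0.678), and 4 rose and 3 fell with the replicate block. Of 13 tested hypoxia genes cah-4 rose and 0 fell, 1 also adjusted over the list alone (median 0.11, adjusted p = 0.777), and 2 rose with the replicate block. Of 32 tested moulting genes 0 passed, also adjusted over the list alone (median 0.16, adjusted p = 0.678), and 6 rose and 2 fell with the replicate block. Of 15 tested genes of the excretory cell and coelomocytes 0 passed, also adjusted over the list alone (median 0.20, adjusted p = 0.532), and 4 rose with the replicate block. The median, the mean and the camera direction differed in sign for the C-type lectin, mitochondrial unfolded protein response, hypoxia, intestine, lysosome and beta-oxidation lists. The median changed sign with rescaling for the lysosome, hypoxia, fatty acid synthesis and beta-oxidation lists. The sentinels fat-6 (adjusted p = 0.0983) and act-5 (adjusted p = 0.289) did not pass. The sentinels fat-7 (adjusted p = 0.125), gpdh-1 (adjusted p = 0.057) and elt-2 (adjusted p = 0.0936) did not pass either, but did with the replicate block (adjusted p = 0.00509, 0.02 and 0.0307), and gpdh-1 also passed with median-of-ratios and quantile scaling (adjusted p = 0.0499 and 0.0431).

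**Figure D4:**
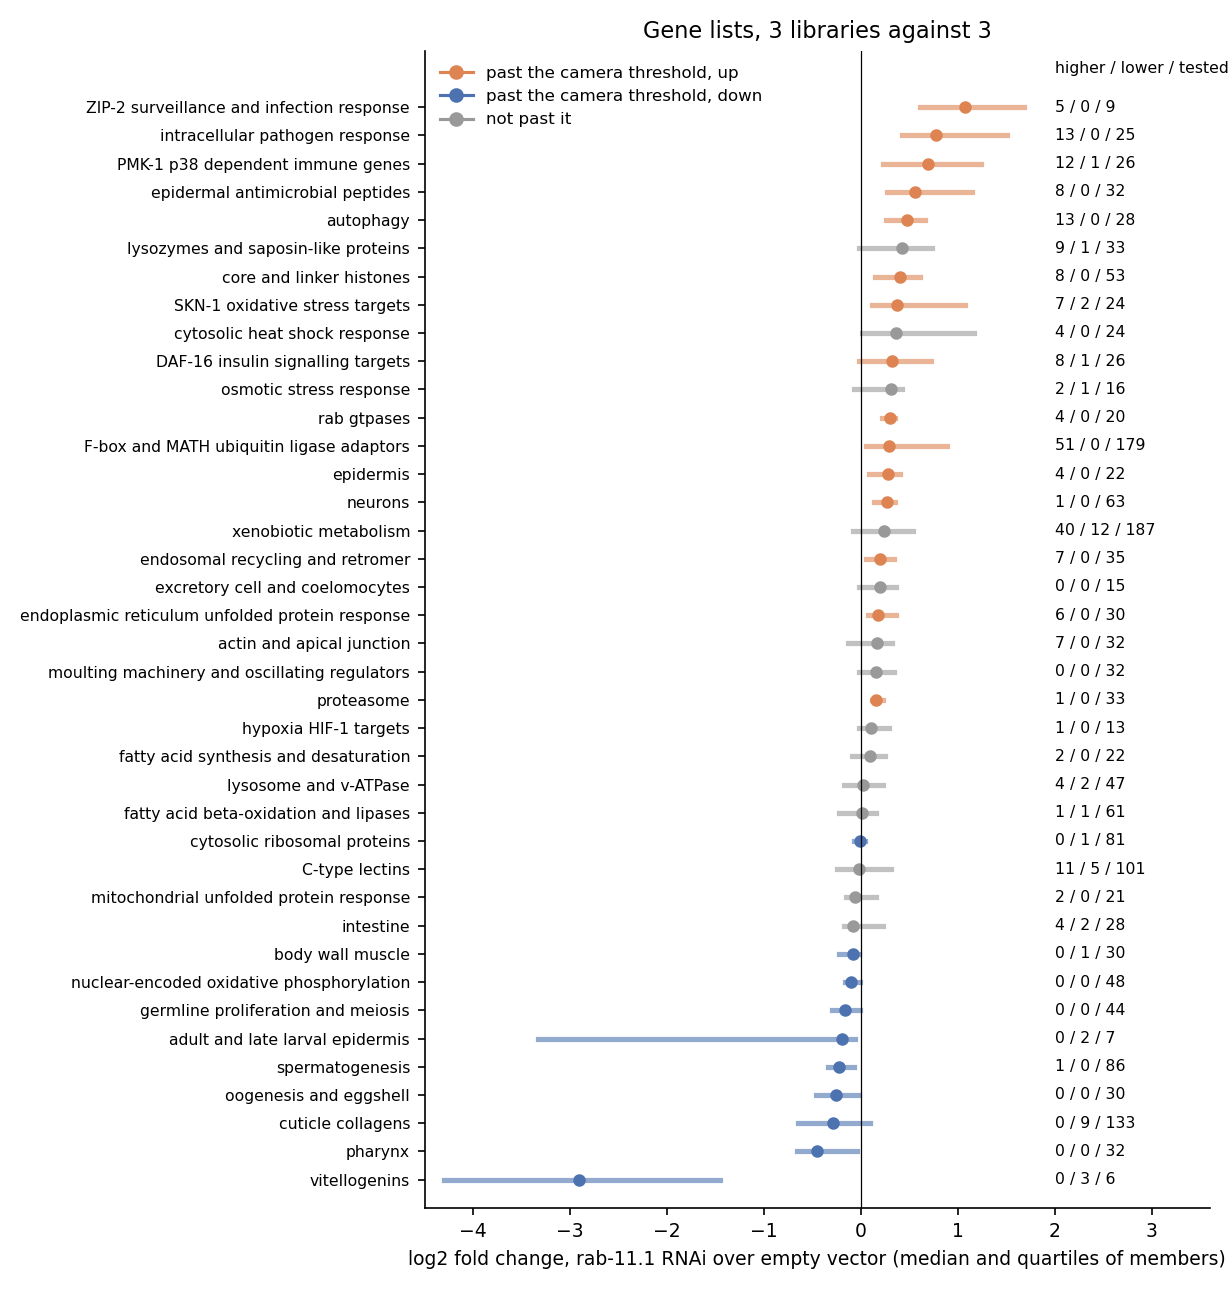
Median log2 fold change (points) and quartiles (lines) of rab-11.1 RNAi over empty vector for the tested genes of each of the 39 lists, coloured by the camera result with its preset correlation, with the numbers of genes higher, lower and tested. The ZIP-2 list (median 1.08) and the intracellular pathogen response (median 0.78) lie highest and the vitellogenins (median -2.91) lowest.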

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

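Median-of-ratios scaling, quantile normalization, voom, thinning, both settings that left out pairs of libraries and the germline covariate were chosen after the result was seen, and the other settings before. Of the 1245 genes changed (1097 higher, 148 lower), the replicate block kept all and called 2906 (2288 higher, 618 lower), and of the lists it ended the call of DAF-16 targets alone (adjusted p = 0.0978, and 0.00354 to 0.493 over all settings). It ended no call of a named gene, added 24 among the genes chosen by the naming rule and added no list. Lower genes numbered 97 with no filter and 88 without the trend. A fold of at least 2 left 436 (398 higher, 38 lower). Median-of-ratios scaling gave 552 higher and 284 lower, and quantile normalization gave 773 (524 higher, 249 lower), 663 of them shared. Leaving out both replicate 2 libraries gave 2119 (1652 higher, 467 lower), 1088 of them shared, the block without both replicate 3 libraries gave 915 (753 higher, 162 lower), 628 of them shared, and the germline index as a covariate gave 2306 (1930 higher, 376 lower), among them all 1245. With 1 library left out the count ran from 284 (264 higher, 20 lower), without empty vector replicate 3, to 1063 (938 higher, 125 lower), without empty vector replicate 2. Between these lay 343 without empty vector replicate 1, and 392, 681 and 647 without rab-11.1 RNAi replicates 1, 2 and the library labelled 3. A group left with 2 libraries was assumed to vary like the other. The rab-11.1 level, as a log2 fold change, ran from -1.49 to -0.39 with 1 library left out. It passed without the library labelled rab-11.1 RNAi replicate 3 (-1.49, adjusted p = 0.00557) and with the block and both replicate 3 libraries left out (-1.48, adjusted p = 0.00997), and in no other setting (highest adjusted p = 0.782). The number of lists passing was 0 with an estimated correlation and 16 with fry, 13 shared with the 25 of camera, and ran from 21 to 28 in the other settings. The ribosomal list reversed with quantile normalization (adjusted p = 0.188, up, and 1.02e-08 to 0.83 over all settings). The cause of these changes was not tested, except that fits without a library hold fewer samples. Of 2580 results for single named genes across settings 2237 kept direction and side of the threshold, 266 lost their call, 77 gained 1 and 0 reversed. Of 818 for lists 730 kept both, 64 lost their call, 23 gained 1 and 1 reversed. Depth limits genes near 1 RPKM, where a read at 1 kb is 0.0331 to 0.0436 RPKM.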

Other observations

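All tests in this part were chosen after the result was seen, except the splits for the gene lists. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave as many as the 1245 called genes, and the highest other gave 0. For the lists 1 split, again the real split, gave as many as 25, and the others gave 11 to 21. Camera with its preset correlation thus passed many lists also in splits that mix the groups. Passing it does not by itself tie a list to rab-11.1 RNAi. With 10 splits the share cannot fall under 0.05. If the replicate numbers pair the samples, only the splits that part every pair count, so the share can fall less far still. Among these the real split gave 25 lists and the others 15 to 18.

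The library labelled rab-11.1 RNAi replicate 3 held more rab-11.1 than any empty vector library. That it was an empty vector library under a wrong label is argued against. Of 372 genes called at a fold of 2 or more without that library, 94.6% lay nearer the other rab-11.1 RNAi libraries in it. The test compared it with the libraries of these groups alone, so it cannot decide on a wrong label from some other sample. Animals in which RNAi failed would on their own bring the level up to that of the empty vector at most. The measured level lay 0.62 above the highest empty vector library on the log2 scale, where the SD of the empty vector libraries was 0.025. Failed animals together with counted reads of the RNAi trigger could reach such a level, so this test cannot decide on failed RNAi. For 444 genes called higher without empty vector replicate 2, this library's median log2 difference from the other empty vector libraries was 1.24. Replicates 1 and 2 of its group gave 1.41 and 1.71. For 51 genes called lower the value was -1.49, against -1.74 and -1.59. This library was among those that picked these genes, so these values cannot decide whether RNAi worked in it. Reads of the RNAi trigger counted as the target may be part of the rab-11.1 value. By its excess over the other 2 libraries of the group rab-11.1 ranked 3 of 9890 genes at a mean of 5 RPKM or more, which leaves that explanation open, as values per gene do not show where in the gene the reads lie.

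A lag in development, which may contribute since vitellogenin and adult collagen genes were low, was tested in 2 ways, both chosen after the data were seen. On a scale from 0 (the other empty vector libraries) to 1 (rab-11.1 RNAi), empty vector replicate 2, whose germline lists were low, lay at a median of 0.18 for 444 higher genes (95% bootstrap interval 0.15 to 0.21), under the 0.25 set for a lag, but at 0.5 for 51 lower genes (0.36 to 0.62) and 0.26 for the autophagy list (0.17 to 0.37). The other test, added because the first rests on 1 library and after its outcome was known, took the germline index as a covariate, which kept 95.6% of the median log2 fold change of the 1097 higher genes (93.4 to 97.1) and 96.6% of that of the 148 lower genes (91.9 to 101). The index was lower after rab-11.1 RNAi in each pair of the same replicate number (by 0.34, 0.1 and 0.14). The mean difference of -0.19 was larger than the SD of 0.13 over the pairs but smaller than the unpaired SD of 0.44 within groups. By a rule on the unpaired SD, set after both outcomes were known, the covariate test was not used. A rule on the paired SD would not have set it aside. That 1 library also lay at 0.72 for the vitellogenins and beyond rab-11.1 RNAi for the 3 germline lists (1.75, 1.49 and 1.26), and 1 library excludes nothing, so a lag stays open for the increases and the decreases alike.

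The excess of higher over lower genes may in part come from scaling. Unequal depth is argued against, since 88.2% of the called genes were higher with all libraries thinned to the lowest depth. With median-of-ratios or quantile scaling the lower of the shares was 66%, between the 60% set for scaling as the cause and the 75% set against it, so the part due to scaling cannot be told apart from a true excess. A biological excess of increases was not tested otherwise.

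Among 177 gene families by symbol with at least 8 tested genes, Fisher's exact test (one-sided, adjusted over the families) found more higher genes than in the rest for fbxa (37 of 115, adjusted p = 8.21e-12), vps (11 of 30, adjusted p = 0.000876), fbxc (8 of 17, adjusted p = 0.00114), dod (6 of 10, adjusted p = 0.00173), cyp (14 of 55, beside 3 lower, adjusted p = 0.00236), lec (6 of 11, adjusted p = 0.00236), nhr (29 higher and 1 lower, adjusted p = 0.00576), pals (6 of 15, adjusted p = 0.0145), lys (4 of 8, adjusted p = 0.0413) and atg (5 of 13, adjusted p = 0.0413). It found more lower genes for col (9 of 114, adjusted p = 0.000636) and ugt (6 of 54, adjusted p = 0.00203), although 10 ugt genes were higher. Genes under 1 RPKM in every empty vector library were counted only where all rab-11.1 RNAi libraries reached 1 RPKM. Such genes could be counted as higher but hardly as lower, and the families were not tested without the filter. Genes of a family are not independent, and in these families the sign of the median held with either rescaling except for ugt (0.09, and -0.01 and -0.06 rescaled), while the higher fbxa genes went from 37 to 29 and 22, nhr from 29 to 9 and 4, cyp from 14 to 7 and 7, vps from 11 to 8 and 8, ugt from 10 to 4 and 4, fbxc from 8 to 7 and 7, lec from 6 to 4 and 5, atg from 5 to 1 and 1, and lys from 4 to 4 and 3. The lower ugt genes went from 6 to 9 and 9 and the lower col genes from 9 to 12 and 9.

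Most of the higher vps genes encode the ESCRT machinery, which sorts membrane proteins into vesicles inside endosomes. A list of 18 ESCRT genes, written after these values were seen, had all 18 tested, of which 15 rose and 0 fell (median log2 fold change 0.76), and in 17 the rab-11.1 RNAi libraries all lay above the empty vector libraries, as they did for 3791 of all 13833 features tested. The largest increases were those of did-2, from 80.4 ± 10.9 to 210 ± 45.2 RPKM (2.61-fold, adjusted p = 0.00635), vps-28 (2.48-fold), alx-1 (2.47-fold) and vps-60 (2.28-fold), and vps-25, vps-36 and vps-20 did not pass. With median-of-ratios or quantile scaling 10 rose. Leaving out 1 library, 6, 11 and 5 rose without empty vector replicates 1, 2 and 3, and 10, 11 and 12 without rab-11.1 RNAi replicates 1, 2 and the library labelled 3. The genes did-2, vps-60, alx-1, vps-24 and vps-2 passed in every fit that left out 1 library, with a highest adjusted p of 0.0481. No test was run on this list, as it was picked from its own values.

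Higher genes lay next to each other more often than in shuffled orders. Of adjacent protein-coding tested genes 136 pairs were both higher against a shuffled mean of 74.1 (permutation p = 1e-04, the smallest that 10000 shuffles can give), and 67 against 42.3 with a gap over 1000 bp (permutation p = 4e-04). Lower genes gave 6 pairs against 1.4 (permutation p = 0.002), and 4 against 0.8 with that gap (permutation p = 0.007). On chromosome V 11% of tested genes were higher, against 6.6% to 8% on the other nuclear chromosomes. Neighbouring genes of the same family were not set aside in the shuffles or in these shares, and close paralogues may share reads. The cause of either pattern was not tested. Of 11 mitochondrial-encoded genes tested by limma 0 passed (median log2 fold change -0.1).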
